A study of Rattus norvegicus with 6 samples.

How the data were processed

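Total kidney RNA pooled by genotype and age was measured on 6 arrays with 60-mer probes and 2 colours, 1 array for each of +/+, Cy/+ and Cy/Cy at 3 and at 7 days. Per the labels, RNA was labelled by linear amplification. Cy5 carried the pool that names the sample and Cy3 an age-matched +/+ pool, with no dye swap. The series text names another array product and an older software version than the file headers, which give Agilent Feature Extraction 9.5.1.1 and probe coordinates of build rn3, and the headers were followed. All 3 arrays of 3 days lay on 1 slide and all 3 of 7 days on another, each genotype at 1 fixed position. Age and slide, and genotype and position, therefore cannot be told apart.

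The deposited spot signals and backgrounds are intensity values, scanner brightness without normalization, per the file headers. The processed signals are intensity values that the software had background-subtracted and dye-normalized within each array, per the file headers. The deposited log ratio is log10 of processed Cy5 over processed Cy3, per the file headers, and the authors' series table held the same values (largest difference 0), so its scale, direction and lack of further centring are known. Its column medians were -0.0159 for the 3-day array labelled +/+ and 0 for the other 5. A deposited p-value per spot comes from the software's error model, per the file headers.

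In R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, mean spot signals were corrected with normexp (offset 50) against the median local background and normalized within each array by loess, with control spots and spots with the software's outlier flags at weight 0. Those flags covered 125 to 192 spots per array, and 58 probes had no usable spot on an array. At most 1 spot per array was saturated. Spots of a probe were averaged (263 probes had replicate spots, and 253 of them gave a correlation between duplicates of 0.862 to 0.998). A probe was kept when well above background in either channel on at least 2 arrays, which left 30934 of 41012 probes. Probes were named through their accession, symbol or synonym in a gene table of rat assembly GRCr8, used for names only. Of the probes 10735 matched by their own accession, 117 by another accession, 5542 by symbol and 3704 by synonym, 41 matched several genes and were left unnamed, and 20873 had no match. A gene was represented by its brightest probe, giving 12818 genes. Probes of 1 gene disagreed in direction or size for Calb1, Alb, Pkhd1, Mycn, Chtf8, Stfa2, Sftpc, Amelx, Crygd and RT1-Bb among the genes named.

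Groups followed the labels. Log2 ratios were fitted with lmFit and eBayes, genotype and age as terms, for Cy/Cy and Cy/+ against +/+ and for Cy/Cy against Cy/+ (2 residual degrees of freedom before moderation, prior 3.07), as a slope per Cy allele (3 residual degrees of freedom), and as the difference of that slope between ages. Subtracting the array labelled +/+ was planned to remove dye bias. Because that array lay far from its own reference, each mutant ratio was also tested against 0 (2 residual degrees of freedom, prior 3.94), chosen beforehand as another way to run the comparison and given here as a result of its own. That test takes the reference as 1 control pool and leaves out its own spread. P-values were adjusted by Benjamini-Hochberg with 0.05 as threshold. Where a group was not well above background on any array, a fold is given as "at least", from the mean of the bright group against the higher of the array's lowest signal well above background and the probe's own signal, on values of that channel normalized between arrays. It leaves out the reference channel, so it can exceed the fitted difference of ratios, and is open to dye bias.

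For the change from 3 to 7 days, channels were separated after loess and Aquantile normalization. In the reference, genes at least 2-fold apart with no overlap between the 3 hybridisations of each age were listed, without a test because the 3 are taken as hybridisations of a single pool, which the labels do not state. Lower Cy3 correlations of the arrays labelled +/+ with the others of their age leave this in doubt. A limma fit over the reference, Cy/+ and Cy/Cy pools with the pool as a block was added after the data were seen. Its reference values came in part from Cy3 of the same arrays as the mutant pools. The 3 values per age are therefore not independent repeats.

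For this study 30 gene lists were fixed, for nephron segments, other cells and tissues, RXR signalling, cystic disease and metabolism, and 8 lists of further tissues were added after the transcripts of the arrays labelled +/+ had been seen. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, each adjusted over the 30 lists. With an estimated correlation camera rests on the 2 residual degrees of freedom, and it called 0 lists in every fit. A list that does not pass there is therefore not shown to be unshifted. Medians were also ranked among 10000 random lists matched on intensity in 20 bins. Named genes were the 12 largest rises and 12 falls past the threshold and the same way at both ages for Cy/Cy, 6 and 6 for Cy/+, 4 and 4 for the difference between ages and for Cy/Cy against Cy/+, 8 and 8 for the reference, up to 4 members per list, and Anks6, Pkd1, Pkd2, Pkhd1, Rxra, Rxrb and Rxrg always. The groups, tests, lists, naming rule and most other settings were set before the data were examined. For the mutant ratios and the 3 pools the same rule was applied afterwards, with 12 and 12.

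Each fit was tested on simulated data with independent genes. The genotype and slope fits took the residual spread of the genotype fit, and the others that of the mutant ratio fit. The slope fits' own residual also holds departure from a straight line, so their recovery may not hold in these data. With 100 genes changed by log2 1 and 100 by log2 2 among 12818, Cy/Cy against +/+ recovered 82 and 99 with 11 false calls, Cy/+ against +/+ 89 and 99 with 19, Cy/Cy against Cy/+ 87 and 98 with 16, the slope 100 and 100 with 22, its difference between ages 88 and 100 with 13, each mutant ratio 100 and 100 with 20 for Cy/+ and 22 for Cy/Cy, the 4 mutant arrays 98 and 100 with 40, and the 3 pools 99 and 100 with 17. The 2-fold rule recovered all 100 at log2 2 with 26 false calls. Its 3 simulated hybridisations of an age were identical copies, so the no-overlap condition was always met and was not tested. The simulated pools had independent noise, whereas the reference measured here shares arrays with the mutant pools. Neither recovery need hold in these data. A shift of log2 1 in 31 genes was found by camera with 0 other lists called. With independent genes, the camera run cannot test the preset correlation.

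Alternatives were the software's log ratios, the series table, median centring, scaling between arrays, no background correction, no and a strict filter, the mean of probes, an intensity trend with robust prior, each array left out, no age term, an adjusted p of 0.10, and 2-fold rules. Median centring moved the median of all genes to between 0.198 and 0.371 in log2 on the 6 arrays, against 0.00595 to 0.0831 after loess, and the software's log ratios moved it to -0.151 and -0.106 on the arrays labelled +/+. No genome of build rn3 was used, so coordinates are those of the probes in the files and no sequence context is given. List medians move with the scaling, in size and for some lists in direction. Some genes are not reported here.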

Results

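Kidney transcripts of the Han:SPRD Cy rat, a strain with inherited polycystic kidney disease caused by a missense mutation in Anks6, were measured on 6 oligonucleotide arrays with 2 colours each. At 3 and at 7 days of age, pooled kidney RNA of wild-type (+/+), heterozygous (Cy/+) and homozygous (Cy/Cy) rats was labelled with Cy5 and set against Cy3-labelled RNA of a +/+ pool of the same age. Each genotype therefore had 1 array at each age, and the ages were the only repeats (n = 2 arrays per genotype). Nothing in the labels states how many animals entered a pool or whether pools were separate, so p-values measure only the spread between these arrays. Each array had 43379 spots other than controls, and the number of arrays limits the precision. The share of spots well above background was 65.0% to 70.0% in Cy3 and 66.8% to 74.8% in Cy5. The median spot signal was 111 to 157 in Cy3 against a background of 36 to 40, and 172 to 336 in Cy5 against a background of 43 to 49. After filtering, 12818 named genes were compared.

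The first question was how far each Cy5 pool lay from its +/+ reference. The arrays labelled +/+, which by their labels set a +/+ pool against a +/+ pool, lay farthest from it. On them 3114 genes (24.3%) at 3 days and 2530 genes (19.7%) at 7 days differed at least 2-fold between the dyes. The arrays labelled Cy/+ had 173 such genes (1.35%) at 3 days and 75 (0.585%) at 7 days, and those labelled Cy/Cy had 20 (0.156%) and 12 (0.0936%). These counts depend on the normalization. With the scanner software's log ratios, Cy/+ had 468 and 379 and Cy/Cy 149 and 189, and with median centring Cy/+ had 508 and 575 and Cy/Cy 103 and 164. The 7-day array labelled +/+ had 3947 with the software's log ratios. The SD of the log2 ratios was 1.29 and 1.12 on the arrays labelled +/+, 0.349 and 0.246 on those labelled Cy/+, and 0.181 and 0.166 on those labelled Cy/Cy. Log2 ratios of the arrays labelled +/+ at 3 and 7 days correlated across genes with r = 0.924 (0.840 by ranks), genes not being independent replicates. Because these data go against their label, they are called the arrays labelled +/+ throughout, and every direction drawn against them holds only as far as that label does.

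Transcripts of tissues other than kidney were high in Cy5 on the arrays labelled +/+. The 10 measured skeletal muscle genes had a median log2 ratio of 4.51 at 3 days and 4.16 at 7 days, and the 9 adipose genes 3.93 and 4.20. Erythroid genes stood at 2.48 and 1.88, and adrenal genes at 1.19 and 1.25. In lists written after the data were seen, the medians at 3 and 7 days were 4.75 and 4.39 for liver, 4.64 and 4.27 for exocrine pancreas, 4.62 and 4.31 for intestine, 4.16 and 3.26 for lung, 3.85 and 3.35 for skin, and 2.64 and 1.07 for brain. Except for liver, most members of these lists were not well above background in the reference of the mutant arrays (members above it: liver 10 of 14, lung 1 of 7, exocrine pancreas 4 of 16, intestine 2 of 6, skin 3 of 7, brain 5 of 14), so background limits these ratios and their size is uncertain. The lens list stood at 2.06 and 4.28, and 2 germ cell genes at 0.25 and 0.20. Albumin (Alb), the main plasma protein made by liver, had log2 ratios of 6.93 and 7.48, and the surfactant protein Sftpc of lung 7.09 and 6.31. Nephron lists were low on the same arrays, with medians of -3.48 and -2.81 for the thick ascending limb and -2.34 and -1.92 for the proximal tubule.

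**Figure D1:**
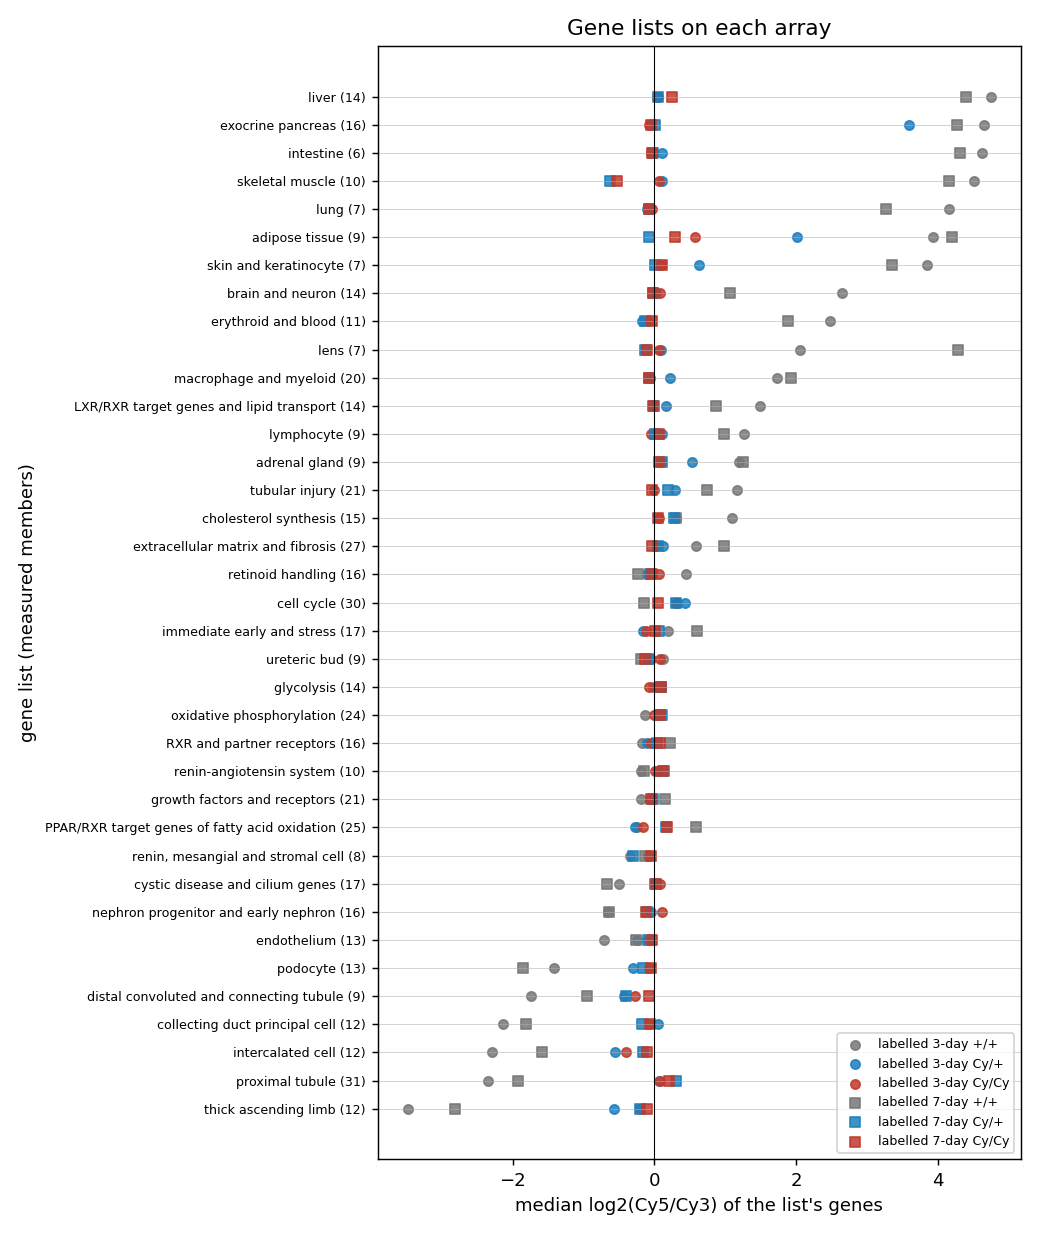
Median log2(Cy5/Cy3) of each gene list (number of measured members in brackets) on each of the 6 arrays, by the group each array is labelled with. The arrays labelled +/+ (grey) lie far from 0 for lists of other tissues (liver 4.75 and 4.39) and for nephron segments (thick ascending limb -3.48 and -2.81), while the arrays labelled Cy/+ and Cy/Cy lie near 0 for most lists.

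The comparison of Cy/Cy with +/+ was planned to ask what the homozygous mutation does to the young kidney. The arrays labelled +/+ lay far from their own reference, so differences from them cannot be assigned to the mutation. Relative to the arrays labelled +/+, genes of kidney tubules were higher on the arrays labelled Cy/Cy. The largest of these differences were in Hao2, a peroxisomal hydroxyacid oxidase (log2 6.66 ± 0.12 SE, n = 2, adjusted p = 6.93e-05, limma, rn3 chromosome 2, 193495810 to 193495869), and in Cltrn, a partner of amino acid transporters (5.64 ± 0.14). The organic anion transporters Slco1a3 (5.37 ± 0.22), Slc22a24 (5.16 ± 0.26) and Slc22a25 (4.83 ± 0.14) followed, with the endocytic receptor Lrp2 (5.04 ± 0.27). The kidney glucose transporter Slc5a2 (4.63 ± 0.13), the acyl-CoA synthetase Acsm2 (4.91 ± 0.12), the amino acid transporter Slc7a13 (4.57 ± 0.17) and the potassium channel subunit Kcnj16 (4.55 ± 0.20) were also higher. Umod, the uromodulin of the thick ascending limb (5.04 ± 0.17, chromosome 1, 177868497 to 177868556), and Slc12a1, its sodium-potassium-chloride cotransporter (4.59 ± 0.17), completed the 12 largest.

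Genes lower on the arrays labelled Cy/Cy than on those labelled +/+ belonged to many tissues. By the fitted difference of log2 ratios, the largest falls among genes measured on both sides were in the cysteine protease inhibitors Stfa3 (-8.97 ± 0.44) and Csta (-7.70 ± 0.35). Then came Atp1b4 of muscle (-7.47 ± 0.18), a further inhibitor, Stfa2 (-7.39 ± 0.21), Sftpc of lung (-7.26 ± 0.12) and the liver fatty acid-binding protein Fabp1 (-7.12 ± 0.22). The lens crystallin Cryba1 (-7.02 ± 0.45), the brain fatty acid-binding protein Fabp7 (-6.85 ± 0.16) and the muscle AMP deaminase Ampd1 (-6.67 ± 0.12) followed. Of 3 more genes, not well above background on the arrays labelled Cy/Cy, only bounds from Cy5 alone are given, which cannot be ranked with the fitted differences. Cyp3a2, a cytochrome P450 of liver, was lower by at least 285-fold, Amelx, the amelogenin of tooth enamel, by at least 1220-fold and the trypsinogen Prss3b by at least 478-fold.

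By list, 30 of 31 proximal tubule genes were higher and 1 lower (median log2 2.29; 30 and 1 adjusted over the list alone; camera adjusted p = 2.32e-18, adjusted p = 0.325 with an estimated correlation). Of the thick ascending limb 11 of 12 were higher and 1 lower (2.99, adjusted p = 3.95e-08), of the collecting duct 11 of 12 higher (1.96, 6.86e-08), of the distal convoluted and connecting tubule 7 of 9 higher and 2 lower (1.21, 0.00689). These counts were the same adjusted over the list alone, and for each list the adjusted p was 0.393 with an estimated correlation. Intercalated cell genes were higher in 8 of 12 and lower in 1 (10 and 2 adjusted over the list alone, median 1.60, 3.96e-05). Podocyte genes were higher in 9 of 13 (9 adjusted over the list alone, 1.31, 1.54e-05), both lists with an adjusted p = 0.325 with an estimated correlation. Cystic disease and cilium genes were higher in 9 of 17 (10 adjusted over the list alone, adjusted p = 0.000186). Early nephron genes were higher in 8 of 16 (9 adjusted over the list alone, 0.00153) and endothelial genes in 6 of 13 (9 adjusted over the list alone, 0.00527), each with 1 lower. These lists stood at adjusted p = 0.393 with an estimated correlation. On the same arrays labelled +/+ the median of 10 skeletal muscle genes was 4.51 and 4.16.

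Lists of other cells and tissues were lower on the arrays labelled Cy/Cy. All 10 skeletal muscle genes (median -4.49; camera adjusted p = 1.06e-07, adjusted p = 0.325 with an estimated correlation) and all 9 adipose genes (-3.46, 0.000381, adjusted p = 0.515 with an estimated correlation) fell. So did 18 of 20 macrophage and myeloid genes (19 adjusted over the list alone, -1.84, 8.15e-08), 9 of 11 erythroid genes (10 adjusted over the list alone, -2.18, 3.94e-05) and 8 of 9 lymphocyte genes (9 adjusted over the list alone, -1.06, 0.000938). Of 9 adrenal genes 6 fell (8 adjusted over the list alone, -1.79, 0.00500), and of 14 genes of lipid transport and LXR/RXR targets 9 fell (9 adjusted over the list alone, -1.12, 0.00289). All 5 lists stood at adjusted p = 0.393 with an estimated correlation. Tubular injury genes fell in 13 of 21 and rose in 2 (13 and 3 adjusted over the list alone, -1.27, 0.0207, adjusted p = 0.515 with an estimated correlation). Matrix genes fell in 15 of 27 and rose in 3 (16 and 4 adjusted over the list alone, -0.71, 0.0161). Cholesterol synthesis genes fell in 6 of 15 (7 adjusted over the list alone, -0.62, 0.0173), both lists at adjusted p = 0.667 with an estimated correlation. At 3 and 7 days the tubular injury median was 1.17 and 0.741 on the arrays labelled +/+ and -0.00805 and -0.0309 on those labelled Cy/Cy. Macrophage genes stood at 1.73 and 1.93 against -0.0579 and -0.0784, and matrix genes at 0.586 and 0.98 against 0.0416 and -0.03. For these lists the fall therefore comes from the arrays labelled +/+. The medians move with the scaling. With the scanner software's log ratios lymphocyte genes stood at -2.88 and adrenal genes at -3.49, and after scaling between arrays at -0.541 and -1.10.

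In all, limma called 4674 genes (36.5%) at adjusted p under 0.05, 1551 higher and 3123 lower on the arrays labelled Cy/Cy. Without the 3-day array labelled Cy/Cy it called 2102, and without the 7-day one 2551. Camera called 19 of the 30 lists with its preset correlation and 0 with an estimated one, and fry called 17. With the scanner software's own log ratios the calls numbered 5404, of which 49.1% were higher, against 33.2% here. Without the arrays labelled +/+, testing the Cy/Cy ratio to its own reference against 0, no gene passed, and Slc12a1, Fabp1, Cyp3a2, Fabp7 and Ampd1 changed sign.

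Set against its own +/+ reference pool, the Cy/Cy kidney showed small ratios. The largest sulfotransferase ratio was that of Sult1c2a, 2.19-fold above the reference (log2 1.13 ± 0.07 SE, n = 2, adjusted p = 0.0611, limma, chromosome 9, 1030881 to 1030940), the smallest adjusted p in this comparison. The gluconeogenic enzyme Fbp1 (0.85 ± 0.10, adjusted p = 0.252) and Hao2 (0.65 ± 0.18, adjusted p = 0.442) lay above the reference, and the ammonia transporter Rhcg (-0.53 ± 0.10, adjusted p = 0.328) below it. Of the 31 proximal tubule genes, 7 passed when adjusted over the list alone and 0 over all genes (median 0.16; camera adjusted p = 7.87e-06, adjusted p = 0.75 with an estimated correlation). Cell cycle genes had a median of 0.19 with 0 members called either way (1.22e-06, adjusted p = 0.75 with an estimated correlation).

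The intercalated cell list lay lower (median -0.24, 2 members adjusted over the list alone, camera adjusted p = 7.87e-06), as did the thick ascending limb (-0.12, 0.0037), the distal tubule (-0.16, 0.0037), skeletal muscle (-0.28, 0.0474) and immediate early genes (-0.06, 0.0442), each with an adjusted p = 0.75 with an estimated correlation. Median centring instead of loess raised the median of all genes by a shift that differs between genes. Relative to that median, the intercalated list stood at -0.112, the distal tubule at -0.176, the immediate early list at -0.102 and skeletal muscle at -0.464, and the thick ascending limb at 0.0122. The lists that lay higher moved further up, the proximal tubule from 0.154 to 0.422 and the cell cycle from 0.179 to 0.314. Limma called 0 genes, with 1183 at an unadjusted p under 0.05. Camera called 7 of the 30 lists, and 0 with an estimated correlation, and fry called 0. Median centring, which leaves intensity-dependent dye bias in place, called 6355.

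Relative to the arrays labelled +/+, the arrays labelled Cy/+ differed in nearly the same way as those labelled Cy/Cy. Hao2 (log2 6.84 ± 0.12 SE, n = 2, adjusted p = 7.00e-05, limma), Cltrn (5.88 ± 0.14), Slc22a24 (5.80 ± 0.26), Slco1a3 (5.66 ± 0.22), Slc7a13 (5.51 ± 0.17) and Lrp2 (5.37 ± 0.27) were the 6 highest. Stfa3 (-9.19 ± 0.44), Csta (-7.84 ± 0.35), Alb (-7.66 ± 0.65), Atp1b4 (-7.60 ± 0.18), Stfa2 (-7.42 ± 0.21) and Fabp1 (-7.36 ± 0.22) were the 6 lowest with a measured level. Proximal tubule genes were higher in 28 of 31 and lower in 1 (29 and 1 adjusted over the list alone, camera adjusted p = 6.15e-17). Skeletal muscle genes were lower in 10 of 10 (10 adjusted over the list alone, 1.57e-07), both lists at adjusted p = 0.417 with an estimated correlation. Cell cycle genes were higher in 9 of 30 (6 adjusted over the list alone; 0.000398, adjusted p = 0.61 with an estimated correlation).

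In all, 4829 genes (37.7%) passed, 1673 higher and 3156 lower. Without the 3-day array labelled Cy/+ 2257 passed, and without the 7-day one 2464. Camera called 18 of the 30 lists with the preset correlation and 0 with an estimated one, and fry called 20. The Cy/+ and Cy/Cy comparisons shared 1343 genes called higher and 2917 called lower, where independent lists would share 202 and 769. Their fitted changes correlated at r = 0.987 across genes (covariance 1.36), against 0.493 (0.0163) simulated with no effect. Both comparisons subtract the same arrays labelled +/+. Neither the independent lists nor the simulation holds the distance of those arrays from their reference. The ratios of the arrays labelled +/+ had a covariance of 1.33 between ages. Those labelled Cy/+ and Cy/Cy shared only 0.0324 at 3 days and 0.0261 at 7 days. Most of the shared change therefore comes from the subtracted arrays. Against their own reference, without the arrays labelled +/+, 933 genes passed. The scanner software's log ratios gave 5535 calls, 50.7% of them higher, against 34.6% here.

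Set against its own +/+ reference pool, the Cy/+ kidney had its largest rise among called genes in Hnmt, which methylates histamine. It was 5.23-fold higher (log2 2.39 ± 0.29 SE, n = 2, adjusted p = 0.0176, limma, chromosome 3, 2058230 to 2058289), with log2 ratios of 3.07 at 3 days and 1.71 at 7 days. The sulfotransferases Sult1c2a (3.75-fold, log2 1.90 ± 0.07, adjusted p = 0.0029) and Sult1c2 (3.08-fold, 1.62 ± 0.09), neighbours of related sequence whose probes may not tell them apart, rose, and so did Gclc, the catalytic subunit of glutathione synthesis (3.34-fold, 1.74 ± 0.10, adjusted p = 0.00672). The asparaginase Aspg (3.14-fold, 1.65 ± 0.13), Sfnl1 (2.70-fold), Dleu7 (2.69-fold), the protease Prss30 (2.68-fold), the phosphatase Ptprq (2.64-fold), Slc7a13 (2.63-fold) and the cytokine Il24 (2.48-fold, 1.31 ± 0.21, adjusted p = 0.0306) were also among the largest rises.

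The largest fall was in Calb1, the calcium-binding calbindin of the distal tubule (log2 -1.65 ± 0.13, adjusted p = 0.00806, chromosome 5, 30479753 to 30479812), although its 4 probes ranged from -1.65 to 0.54. The prostaglandin synthase Ptgs2 (-1.48 ± 0.31, adjusted p = 0.0477), the globin Hbb (-1.36 ± 0.13), the defensins Defa5 (-1.36 ± 0.22) and RatNP-3b (-1.15 ± 0.17), and S100g, another calcium-binding protein (-1.28 ± 0.11, adjusted p = 0.00925), also fell. Cdkn1c, an inhibitor of the cell cycle, fell by 1.12 on the log2 scale (SE 0.16, adjusted p = 0.0237), and Dhrs2l1 (-1.35 ± 0.19), Spink1l (-1.34 ± 0.16), Cpne4 (-1.13 ± 0.08), Gstm5 (-1.13 ± 0.19) and Sorcs3 (-1.11 ± 0.10) completed the 12. These genes were chosen by the rule fixed for the other comparisons, applied here after the data were seen.

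**Figure D2:**
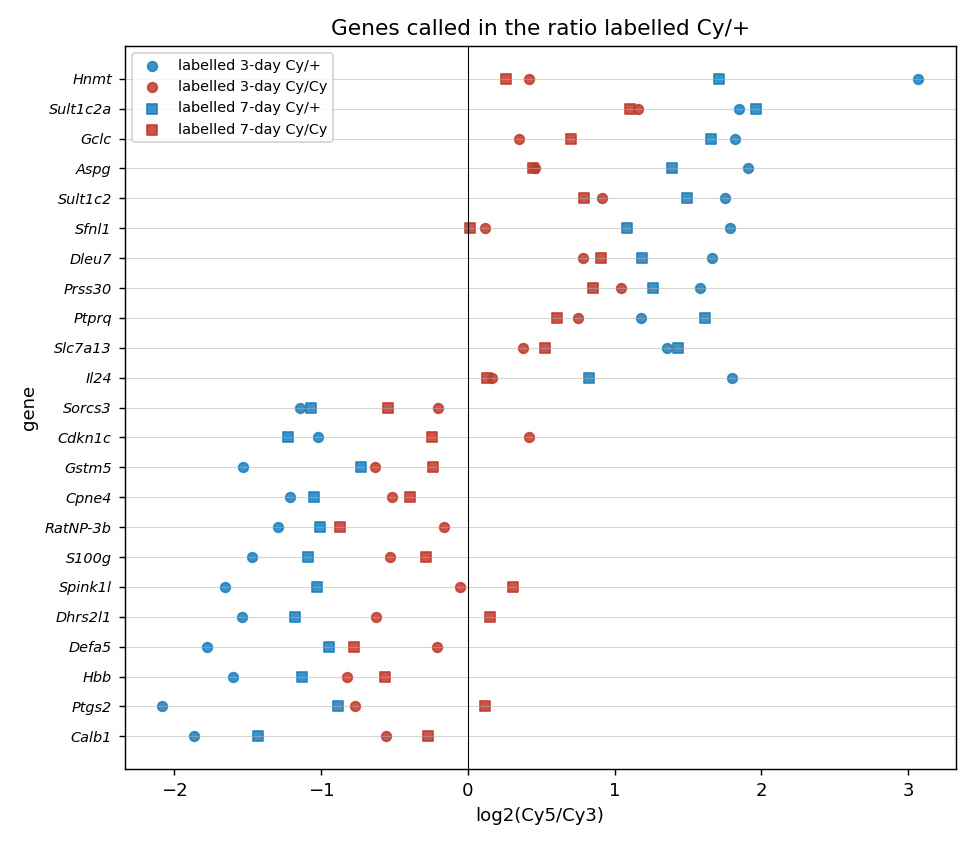
Log2(Cy5/Cy3), mutant pool over its +/+ reference, of 23 genes with the largest called rises and falls on the arrays labelled Cy/+, shown on the 4 arrays labelled Cy/+ and Cy/Cy at 3 and 7 days. Hnmt reached 3.07 and 1.71 on the arrays labelled Cy/+ and 0.42 and 0.26 on those labelled Cy/Cy, and Calb1 -1.86 and -1.43 against -0.56 and -0.27. Calb1 is shown by its brightest probe, and its probes disagreed in direction in the Cy/+ ratio.

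The gene and list values of the Cy/+ ratio rest in part on its 3-day array, which also carried pancreatic and fat transcripts (exocrine pancreas median log2 ratio 3.59, adipose 2.01). Against 933 calls in all, 87 genes passed without that array and 0 with the scanner software's log ratios, and fry called 0 of the 30 lists where camera called 10. With the software's log ratios the list medians kept the signs given below, at 0.366 for the cell cycle, 0.289 for cholesterol synthesis, 0.229 for tubular injury, -0.5 for the thick ascending limb and -0.6 for the distal tubule. Under median centring, relative to the median of all genes, the cell cycle list moved from 0.341 to 0.542, cholesterol synthesis from 0.244 to 0.457 and tubular injury from 0.224 to 0.431. The cell cycle list lay higher, with 7 of 30 members called higher and 0 lower (18 and 0 adjusted over the list alone; median log2 0.36; camera adjusted p = 1.73e-09, adjusted p = 0.745 with an estimated correlation). Its median was 0.426 at 3 days and 0.305 at 7 days. Among them were Rrm2, a ribonucleotide reductase subunit (2.15-fold, adjusted p = 0.0155), the replication factors Mcm4 (0.77 ± 0.09) and Pcna (0.64 ± 0.07), and Cdkn3 (0.73 ± 0.13). Cholesterol synthesis genes rose in 5 of 15 (9 adjusted over the list alone; median 0.26; 2.53e-05, adjusted p = 0.745 with an estimated correlation), among them the squalene enzymes Sqle (0.47 ± 0.07) and Fdft1 (0.37 ± 0.07), Cyp51 (0.48 ± 0.09) and the sterol sensor Insig1 (0.66 ± 0.10). Tubular injury genes rose in 5 of 21 and fell in 3 (9 and 3 adjusted over the list alone; median 0.24; 0.0353, adjusted p = 0.745 with an estimated correlation). Osteopontin, Spp1, rose 2.40-fold (1.26 ± 0.13, adjusted p = 0.0138) and the injury receptor Havcr1 2.28-fold (1.19 ± 0.24, adjusted p = 0.0443), Krt20 stood at 0.79 (adjusted p = 0.0531), and the trefoil peptide Tff3 fell (-0.76 ± 0.09).

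The lists of 3 distal nephron segments and of podocytes lay lower on the arrays labelled Cy/+, with at most 5 members of each called, and the collecting duct list had 0 of 12 called. In the thick ascending limb 5 of 12 fell (7 adjusted over the list alone; median -0.44; camera adjusted p = 2.53e-05), among them the calcium-sensing receptor Casr (-1.02 ± 0.11, adjusted p = 0.0150) and Slc12a1 (-0.71 ± 0.13, adjusted p = 0.0395). In the distal convoluted and connecting tubule 4 of 9 fell (6 adjusted over the list alone; -0.41; 2.53e-05), with Calb1, S100g and the kallikrein Klk1 among them. Calb1 counts there by its brightest probe, although its probes disagreed in direction. In intercalated cells 5 of 12 fell (5 adjusted over the list alone; -0.35; 0.000173), among them the anion exchanger Slc4a1 (-1.01 ± 0.12, adjusted p = 0.0169), Rhcg (-0.65 ± 0.10) and the proton pump subunit Atp6v1b1 (-0.56 ± 0.11). Of 13 podocyte genes 2 fell (7 adjusted over the list alone; -0.29; 0.000348), including nephrin, Nphs1 (-0.58 ± 0.10). Each of these lists had an adjusted p = 0.745 with an estimated correlation. At 3 and 7 days the medians were -0.566 and -0.196 for the thick ascending limb, -0.425 and -0.402 for the distal tubule, -0.558 and -0.164 for intercalated cells, and -0.297 and -0.158 for podocytes. Under median centring the thick ascending limb (0.09) and the podocyte list (0.14) turned above 0 but stayed below the median of all genes, at -0.21 and -0.16 relative to it.

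Proximal tubule genes moved both ways, 8 of 31 higher and 1 lower (13 and 5 adjusted over the list alone; camera adjusted p = 0.207), with the angiotensin-converting enzyme Ace (0.87 ± 0.07, adjusted p = 0.00806), Lrp2 (0.87 ± 0.14) and Hao2 (0.84 ± 0.18) among those that rose. Erythroid genes fell in 3 of 11 and rose in 1 (4 and 1 adjusted over the list alone, median -0.14, 0.0152). The steroid enzymes Cyp17a1 (0.92 ± 0.10) and Cyp11a1 (0.63 ± 0.11) rose among 9 adrenal genes (2 adjusted over the list alone, 0.26, 0.0161), each list at adjusted p = 0.745 with an estimated correlation. The adrenal direction depends on the scaling, since relative to the median of all genes the list stood at 0.241, at 0.978 with the software's log ratios and at -0.301 under median centring. The erythroid list stood at -0.155, -0.438 and -0.59. On the arrays labelled Cy/+ the adrenal median was 0.536 at 3 days, where pancreatic and fat transcripts were also high, and 0.102 at 7 days. Collecting duct genes had 0 calls (camera adjusted p = 0.396), and so had the lymphocyte list (0.396), skeletal muscle (0.160) and the ureteric bud (0.635), with 0 also adjusted over the list alone. Endothelium (0.153) and glycolysis (0.312) had 0 calls over all genes, and 1 higher with 4 lower and 2 higher adjusted over the list alone. Oxidative phosphorylation had 2 genes higher of 24 (5 adjusted over the list alone, 0.0778). The matrix list had 3 higher and 1 lower of 27 (0.346), macrophages 2 higher of 20 (0.312) and early nephron genes 1 higher of 16 (0.237), all with the same counts adjusted over the list alone. Growth factors had 3 lower of 21 (4 adjusted over the list alone, 0.3) and immediate early genes 1 lower of 17 (1 higher and 2 lower adjusted over the list alone, 0.306). Stromal cell genes had 1 higher and 2 lower of 8 (1 and 4 adjusted over the list alone, 0.306) and the renin-angiotensin system 2 higher of 10 (2 higher and 1 lower adjusted over the list alone, 0.312).

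Among the 4 arrays labelled Cy/+ or Cy/Cy, pancreatic and fat transcripts were highest on the 3-day array labelled Cy/+. The exocrine pancreas list, written after the data were seen, had a median log2 ratio of 3.59 there, with Amy2a3 and Prss3b both at 5.34 and 14 of 16 members at least 2-fold higher. At 7 days its median on the array labelled Cy/+ was 0.00488. Adipose genes stood at 2.01 there at 3 days and at -0.08 at 7 days, with 1 of 9 called higher (1 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.745 with an estimated correlation). In all, limma called 933 genes (7.28%), 571 higher and 362 lower. Of these, 861 had the same sign on the array labelled Cy/Cy at 3 days and 888 at 7 days. Across all genes the ratios labelled Cy/+ and Cy/Cy correlated at 0.512 at 3 days and 0.639 at 7 days. The direction of most calls is therefore not particular to Cy/+, and by the labels both ratios share a +/+ reference. Without the 3-day array labelled Cy/+ 87 genes passed, the scanner software's log ratios gave 0, and with no dye swap a dye bias of single probes stays in every ratio.

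Directly compared, no gene passed the threshold between Cy/Cy and Cy/+. In simulated data this fit recovered 87 of 100 genes changed by log2 1 and 98 of 100 by log2 2. That recovery did not carry over to these data, where it also missed the 5 genes at least 2-fold apart at both ages. Its residual also holds the change of the arrays labelled +/+ between ages. Limma called 0 genes, with 407 at an unadjusted p under 0.05 and a smallest adjusted p of 0.948. On the 4 mutant arrays alone it again called 0, with 1096 at an unadjusted p under 0.05 and a smallest adjusted p of 0.154. Calb1 was higher on the array labelled Cy/Cy than on that labelled Cy/+ by 1.31 at 3 days and 1.16 at 7 days in log2 units (adjusted p = 0.154), Spink1l by 1.61 and 1.33 (adjusted p = 0.154) and Ptgs2 by 1.31 and 1.00 (adjusted p = 0.187). Hnmt was lower (-2.65 and -1.45, adjusted p = 0.200), as was Sfnl1 (-1.67 and -1.07, adjusted p = 0.187), and these were the 5 genes at least 2-fold apart the same way at both ages. Calb1 is given by its brightest probe, and its probes disagreed in direction in the Cy/+ ratio.

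By list, the thick ascending limb (median difference 0.29; camera adjusted p = 6.42e-07), the distal convoluted and connecting tubule (0.28, 0.000227), podocytes (0.17, 0.000399), intercalated cells (0.11, 0.0334) and erythroid genes (0.11, 0.0334) were higher on the arrays labelled Cy/Cy than on those labelled Cy/+, each at adjusted p = 0.743 with an estimated correlation. Cell cycle (-0.19, 2.91e-07), cholesterol synthesis (-0.24, 0.000513), tubular injury (-0.23, 0.00214), macrophage (-0.19, 0.00251) and adrenal genes (-0.27, 0.00567) were lower, each at adjusted p = 0.743 with an estimated correlation, and adipose genes (-0.48, 0.0459) at 0.751. Camera also called the proximal tubule higher (0.0459, adjusted p = 0.743 with an estimated correlation), although its median difference was 0.00815. Fry called 0 of the 30 lists where camera called 12. The 3-day array labelled Cy/+ also carried the pancreatic median of 3.59 and the adipose median of 2.01.

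A slope per Cy allele asked for genes that follow the number of mutant alleles. Limma called 0 genes, with 4237 at an unadjusted p under 0.05 and a smallest adjusted p of 0.115. For the difference of that slope between 7 and 3 days it called 0, with 39 at an unadjusted p under 0.05. Neither count can show an absence of allele effects. The arrays labelled +/+ lay far from their reference (SD of log2 ratios 1.29 and 1.12), and both mutant groups lay near it. That departure from a straight line went into the residual of both fits. Genes whose Cy/Cy difference from the arrays labelled +/+ shifted most between ages included lens and neural genes, and are given without a test. On the arrays labelled +/+ the lens filament gene Bfsp1 went from a log2 ratio of 0.35 at 3 days to 4.28 at 7 days, Crygn from 2.5 to 4.85, Gja3 from -1.06 to 1.93 and the ubiquitin-like Ubd from -0.26 to 2.46. The hypothalamic peptide gene Pmch went from 5.98 to 1.95, Glal from 4.86 to 0.31 and the histocompatibility gene RT1-Bb from 0.97 to -2.42. The Cy/Cy differences from the arrays labelled +/+ correlated between ages at r = 0.924 across genes, and the Cy/Cy ratios to their own reference at 0.317. For Cy/+ these values were 0.903 and 0.512.

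The mutated gene and the retinoid X receptors, which the series names as its interest, moved little against the reference. Anks6 (chromosome 5, 63643642 to 63645033) stood at 0.06 ± 0.08 in Cy/+ (adjusted p = 0.654) and 0.15 ± 0.08 in Cy/Cy (adjusted p = 0.611), and was higher than on the arrays labelled +/+ by 0.60 ± 0.12 in Cy/Cy (adjusted p = 0.0142) and 0.51 ± 0.12 in Cy/+ (adjusted p = 0.0233). A missense mutation need not change its transcript level, so these values check no label. Of the receptors, Rxrb (chromosome 20, 4955759 to 4955818) fell in Cy/+ (-0.48 ± 0.10 SE, n = 2, adjusted p = 0.0478), and its Cy/Cy ratio was -0.35 ± 0.10 (adjusted p = 0.463). Rxra (chromosome 3, 6689985 to 6690044) was at -0.03 and -0.12 in Cy/+ and Cy/Cy, and Rxrg (chromosome 13, 83312729 to 83312788) at -0.41 ± 0.12 (adjusted p = 0.0966) and -0.23. Against the arrays labelled +/+, Cy/Cy differed by -2.47 ± 0.19 in Rxrg (adjusted p = 0.000675), by -0.24 in Rxra (adjusted p = 0.263) and by 0.12 in Rxrb (adjusted p = 0.675). The Rxrb difference kept its sign in most settings. It turned to -0.243 after scaling between arrays and to -0.186 without the 3-day array labelled +/+, so its direction is uncertain. Pkd1 (chromosome 10, 13847761 to 13847820), the gene of dominant human polycystic disease, had ratios of 0.06 and 0.02. Pkhd1 (chromosome 9, 18840804 to 18840863), that of the recessive disease, had -0.23 ± 0.10 in Cy/+ (adjusted p = 0.213) and -0.06 in Cy/Cy, and was higher in Cy/Cy than on the arrays labelled +/+ by 1.23 ± 0.19 in log2 ratios (adjusted p = 0.00611). In Cy5 it was not well above background on the arrays labelled +/+, so the size of this difference is uncertain. Pkd2 was not analysed here.

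Of 16 RXR and partner receptors, 1 fell in Cy/+ against the reference (2 adjusted over the list alone; camera adjusted p = 0.306), 0 changed in Cy/Cy, and 5 were higher and 5 lower in Cy/Cy than on the arrays labelled +/+ (0.692). No member of the 25 fatty acid oxidation targets of PPAR/RXR passed in either mutant ratio, with 0 at the list alone (0.426 in Cy/+), and against the arrays labelled +/+ 8 were higher and 8 lower in Cy/Cy (0.864). Of the LXR/RXR targets in Cy/+, lipoprotein lipase, Lpl (0.63 ± 0.08), and Apob (0.37 ± 0.08) rose and Pltp (-0.45 ± 0.09) and Abcg1 (-0.37 ± 0.08) fell (3 and 2 adjusted over the list alone; 0.612). Among 16 retinoid handling genes, Stra6, the receptor for retinol-binding protein, rose (0.38 ± 0.07) and the carotene oxygenase Bco1 fell (-0.48 ± 0.07), with 1 and 2 adjusted over the list alone (0.346). Of 17 cystic disease and cilium genes, 2 rose in Cy/+, among them Glis2 (0.80 ± 0.07, adjusted p = 0.00925), and Bbs4 (-0.52 ± 0.09) fell (4 and 2 adjusted over the list alone; 0.612).

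The last comparison followed the kidney from 3 to 7 days. Its 3 pools share arrays and 1 slide at each age and are not independent repeats. The SEs and p-values below therefore do not measure a spread between independent pools. Across the reference, Cy/+ and Cy/Cy pools, C1qtnf12, a secreted metabolic factor, was higher in the pools labelled 7 days (log2 2.54 ± 0.23 SE, n = 3 pools, adjusted p = 0.0249, limma, chromosome 5, 172815846 to 172815905). The nerve growth factor receptor Ngfr (2.04 ± 0.27), the ureteric tip receptor Ret (2.01 ± 0.16, chromosome 4, 154693062 to 154693121), its coreceptor Gfra1 (1.34 ± 0.14), the cyclase Adcy8 (1.71 ± 0.17), the growth regulator Mycn (1.43 ± 0.09, adjusted p = 0.0118), Asprv1 (1.65), Crygn (1.51 ± 0.30), Pdyn (1.47), Spata22 (1.44) and Calb2 (1.34) rose too. The retinol carrier Rbp4 fell (-1.57 ± 0.09, adjusted p = 0.0112), with Adamtsl2 (-1.49), Prpf19 (-1.40), the lipoxygenase Alox15 (-1.36 ± 0.13), the iron genes Tfrc (-1.27 ± 0.11) and Tf (-1.23), Mageh1 (-1.19), Gda (-1.13), the vitamin D hydroxylase Cyp27b1 (-1.12 ± 0.15), Chtf8 (-1.11), and Angptl4 (-1.06 ± 0.22), a target of PPAR.

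Lists of growth and of the forming nephron lay higher at 7 days. Of 30 cell cycle genes 15 rose and 0 fell (22 and 0 adjusted over the list alone; median log2 0.37; camera adjusted p = 8.71e-12), among them Birc5 (0.87 ± 0.17) and Ccne1 (0.83 ± 0.10). Ureteric bud genes rose in 4 of 9, with Wnt11 falling (-0.71 ± 0.07; 6 and 1 adjusted over the list alone; 0.29; 0.00326), cholesterol synthesis genes in 4 of 15 (10 and 1 adjusted over the list alone; 0.27; 0.000239) and retinoid handling genes in 3 of 16, with 1 fall (8 and 1 adjusted over the list alone; 0.21; 0.0231). These 4 lists had an adjusted p = 0.54 with an estimated correlation. Early nephron genes rose in 4 of 16 (6 and 1 adjusted over the list alone; 0.15; 0.0112, adjusted p = 0.685 with an estimated correlation), among them the growth factor Fgf8 (1.00 ± 0.15) and the Notch ligand Dll1 (0.80 ± 0.15). Slc26a4 of intercalated cells (1.03 ± 0.13), Rxra (0.41 ± 0.07, adjusted p = 0.0357) and the vitamin D receptor Vdr (0.37 ± 0.08) rose.

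Macrophage genes fell in 7 of 20 (15 adjusted over the list alone; median -0.46; camera adjusted p = 8.38e-09), with lysozyme, Lyz2 (-0.95 ± 0.10), Ctss (-0.75 ± 0.07) and Cd14 (-0.68 ± 0.07) among them. Immediate early genes fell in 6 of 17 (10 adjusted over the list alone; -0.33; 0.000239), including Fos (-0.95 ± 0.15), Junb (-0.71 ± 0.08) and Atf3 (-0.75). Tubular injury genes fell in 2 of 21 (10 adjusted over the list alone, with 1 rise, -0.24, 0.00278) and LXR/RXR targets in 2 of 14 (6 adjusted over the list alone, with 1 rise, -0.20, 0.0314). Matrix genes fell in 5 of 27 (6 adjusted over the list alone, -0.13, 0.0325) and erythroid genes in 2 of 11 (4 adjusted over the list alone, -0.14, 0.0107). All 6 lists had an adjusted p = 0.54 with an estimated correlation. Glycolysis genes fell in 3 of 14 (6 adjusted over the list alone; -0.21; 0.000954, adjusted p = 0.683 with an estimated correlation) and fatty acid oxidation targets in 3 of 25 (6 adjusted over the list alone, with 1 rise, -0.22, 0.00326, adjusted p = 0.744 with an estimated correlation). The median change of the fatty acid list was -0.462 in the reference alone, so its fall was larger there than over the 3 pools. Its median ratio to the reference went from -0.267 to 0.165 in Cy/+ and from -0.156 to 0.181 in Cy/Cy. The thick ascending limb fell in 1 of 12 (3 adjusted over the list alone, -0.22, 0.000577, adjusted p = 0.685 with an estimated correlation). Of 31 proximal tubule genes 2 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.716). Adipose genes had a median of -1.10 with 0 called (5 lower adjusted over the list alone, 0.00203, adjusted p = 0.685 with an estimated correlation), beside an exocrine pancreas median of -1.77.

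In the +/+ reference alone, 3 hybridisations per age of what the labels give as a +/+ pool, 82 genes differed at least 2-fold without overlap, 44 higher and 38 lower at 7 days, and 52 of them also passed in the 3 pools. That fit holds this same reference as 1 of its pools, so the overlap is not independent. Without the 3-day array labelled +/+ the list held 147 genes (99 higher), and with the software's processed signals 315 (147 higher). C1qtnf12 rose from a normalized log2 intensity of 9.66 ± 0.08 to 12.57 ± 0.02 (technical SD of 3 hybridisations, 1 sample per age), which is 7.52-fold, and Ngfr 7.23-fold, Ret 4.75-fold and Adcy8 3.54-fold. Igfbp1, an insulin-like growth factor-binding protein (4.21-fold, chromosome 14, 87973881 to 87973940), Angptl4 (3.43-fold), Alox15 (3.16-fold), Vnn1 (2.87-fold), Rhoxl (at least 2.75-fold), Adamtsl2 (2.70-fold) and Egf (2.69-fold) were lower at 7 days. The crystallins Crygn (5.62-fold), Cryba1 (4.63-fold), Cryaa (3.54-fold) and Crygd (3.37-fold) were higher, but without the arrays labelled +/+ their log2 differences were 1.53, 1.31, 0.23 and 1.02.

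**Figure D3:**
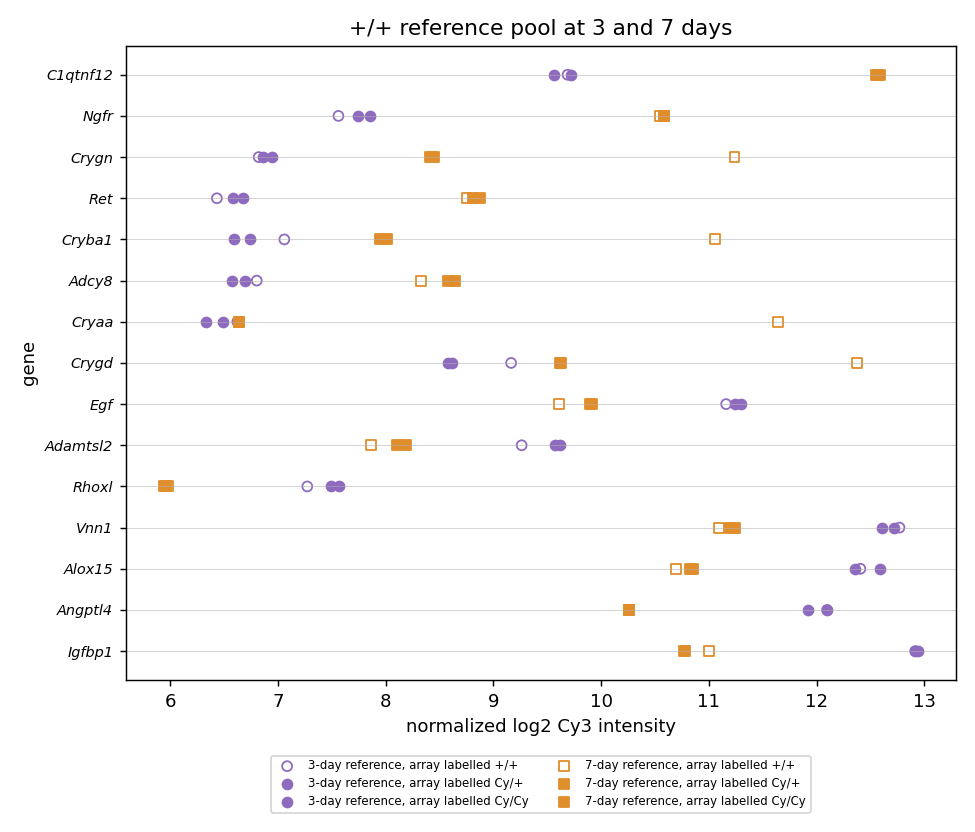
Normalized log2 Cy3 intensity of the +/+ reference pool for 15 genes with the largest differences between ages, 1 symbol per array, circles for 3 days and squares for 7 days; open symbols are the arrays labelled +/+. C1qtnf12 rose 7.52-fold and Igfbp1 was 4.21-fold lower, and the crystallins reached their highest values on the open symbols at 7 days (Cryaa 11.64 against 6.64 on both other arrays).

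For the 3 pools limma called 903 genes, 489 higher and 414 lower, and fry called 0 of the 30 lists where camera called 15. With the reference taken without the arrays labelled +/+, limma called 1231. The 3 pools share arrays and a slide at each age, so the p-values do not measure a spread between independent pools. Each age was a single slide, so age and slide cannot be told apart, and the calls fell to 2 without either array labelled Cy/Cy and numbered 1551 without either labelled Cy/+.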

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

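Tests chosen only after the result was seen were the exchange of +/+ and Cy/Cy judged by spread, the dye effect, the exchange of Cy/+ and Cy/Cy, both carry-over tests, noise judged by the agreement of ages, the genotype effect on pancreas genes and the exchange of ages. The list of 25 fatty acid oxidation targets of PPAR/RXR drew attention because both mutant arrays lay below their reference at 3 days (median log2 ratio -0.267 for Cy/+ and -0.156 for Cy/Cy, under the 2.5th percentile of random lists) and above it at 7 days (0.165 and 0.181, above the 97.5th), a difference between ages that was not tested. The arrays labelled +/+ turned the same way, from -0.245 (percentile 5.26) at 3 days to 0.581 at 7 days. In the reference itself the median change of the list from 3 to 7 days was -0.462. By their labels all arrays of an age share a +/+ reference, and they lay on 1 slide. The turn is therefore not particular to the mutants.

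The arrays labelled +/+ lay farthest from a reference that carries the same label. Uneven hybridisation is argued against by duplicate spots, which correlated at 0.998 and 0.997, and a probe-specific dye effect by the ratios of the arrays labelled Cy/Cy, which share the dyes and followed those labelled +/+ with slopes of 0.0228 and -0.00441. RNA of tissues other than kidney in Cy5 is a candidate explanation, since the highest median among the adrenal, adipose, muscle and erythroid lists was 4.51 at 3 days and 4.20 at 7 days, with Alb at 6.93 and 7.48, Fgg at 5.33 and 4.89 and Tf at 5.17 and 5.24, although the mutant arrays' kidney reference also showed 9 of 10 muscle, 8 of 9 adipose and 10 of 14 liver genes well above background. An exchange of the labels +/+ and Cy/Cy alone brings no liver or lens RNA, but as a part of the pattern it cannot be told apart, because the arrays labelled Cy/Cy had the smallest SD (0.181 and 0.166) and the tubular injury list on the arrays labelled +/+ stood at 1.17 and 0.741, above the bound of 1 at 3 days only. No biological explanation was tested, since the label names the same genotype in both channels.

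The arrays labelled Cy/+ lay farther from the reference than those labelled Cy/Cy, although heterozygotes carry fewer mutant alleles. Carry-over of pancreas into the 3-day pool labelled Cy/+ is a candidate source of its 14 pancreatic transcripts at least 2-fold up (4 of the 16 listed were well above background in the reference, and 0 were on another list), and a genotype effect at both ages is argued against by a 7-day median of 0.00488. Carry-over cannot be the whole cause of the wider spread, because at 7 days the SD of Cy/+ was still 1.48 times that of Cy/Cy. Random noise as the whole cause is argued against by the ratios themselves, which correlated between ages at 0.512 for Cy/+ and 0.317 for Cy/Cy where noise would lower the former, although the Cy/+ minus Cy/Cy difference correlated at only 0.188, between the bounds set beforehand. Exchanged labels at both ages may explain the tubular injury list, higher on the array labelled Cy/+ by 0.294 and 0.228, but a true difference between the genotypes would give the same and stays open, untested.

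The cell cycle, ureteric bud and early nephron lists had higher medians in the pools labelled 7 days than in those labelled 3 days. Nephron formation in the rat, however, ends after birth. No list passed with fry or with camera at an estimated correlation (adjusted p = 0.54, 0.54 and 0.685). The latter rests on 2 residual degrees of freedom and called 0 of the 30 lists in every fit, so it cannot decide whether these lists shifted. In the 3 pools the median change was 0.154 for the early nephron list (4 of 16 genes called higher), 0.292 for the ureteric bud (4 of 9, with 1 lower) and 0.369 for the cell cycle (15 of 30), and Egf, which a maturing kidney makes more of, was 2.69-fold lower in the reference labelled 7 days. An exchange of the age labels of the slides may account for this, but it needs the proximal tubule list to fall as well. Its median was 0.0711 in the 3 pools and -0.115 in the reference alone, so these measures differ in direction. The exchange therefore cannot be told apart from a difference between slides or animals, since each age was 1 slide. A true change between these ages stays open, untested.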

How the results depend on the processing

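Values are counts of genes unless said otherwise. Leaving out both arrays labelled +/+, using every probe, and all settings for the mutant ratios and the 3 pools were chosen after the data were seen. No paired analysis was possible by replicate number because each genotype had 1 array per age. Age, which is also the slide, was a term of the genotype fits and the kind of pool a block in the fit of the 3 pools; without the age term Cy/Cy called 4409 and Cy/+ 4493 against +/+. The slope stayed at 0 genes in 17 alternatives, its difference between ages in 16, and Cy/Cy against Cy/+ in 18 of 19. All slope settings kept an array labelled +/+, so their 0 calls show no absence of allele effects. Of the named genes, Cy/Cy minus +/+ kept its side of the threshold and direction in 463 gene-by-setting values, with 26 weaker, 1 stronger and 13 reversed, Cy/+ minus +/+ in 198, with 5 weaker and 1 reversed, and the Cy/+ ratio in 234, with 62 weaker. Reference genes between ages stayed within their spread in 175 values, with 27 moved and 5 reversed. Signal over background, 66.8% to 74.8% of spots in Cy5, limits what dim probes can show. Where no cause is named, the cause was not tested. With the software's log ratios, and equally with the series table, the Cy/+ ratio called 0, Pkd1 in Cy/Cy minus +/+ turned to 0.0372, the correlation between ages was 0.918 for Cy/Cy and 0.896 for Cy/+, and genes at least 2-fold from the reference numbered 468 (3-day Cy/+), 149 (3-day Cy/Cy), 3947 (7-day +/+), 379 (7-day Cy/+) and 189 (7-day Cy/Cy). Median centring called 6355 for the Cy/Cy ratio and 7295 for Cy/+, gave correlations of 0.929 and 0.910, and 2-fold counts of 508, 103, 575 and 164 on the 4 mutant arrays; it leaves intensity-dependent bias in place. Scaling between arrays called 2 and 409, turned Rxrb to -0.243, gave 0.881 and 0.850, and 2-fold counts of 1654 (3-day +/+), 53 (3-day Cy/Cy), 1500 (7-day +/+), 154 (7-day Cy/+) and 72 (7-day Cy/Cy), since it widens narrow arrays. Without a filter the Cy/Cy ratio called 1, with correlations of 0.919 and 0.899; the strict filter called 1, with 0.920 and 6 genes at least 2-fold on the 7-day array labelled Cy/Cy, where the mean of probes gave 7; the intensity trend called 1. Leaving out each array in turn gave 2102 (without 3-day Cy/Cy) to 5544 (without 7-day +/+) for Cy/Cy against +/+, with 2551 without 7-day Cy/Cy, and 2257 (without 3-day Cy/+) to 5693 (without 7-day +/+) for Cy/+ against +/+, with 2464 without 7-day Cy/+. The Cy/Cy ratio then called 0 to 1, the Cy/+ ratio 87 (without 3-day Cy/+) to 700, the reference 86 to 147 (without 3-day +/+), and the 3 pools 2 (without either Cy/Cy) to 1551 (without either Cy/+), a lone array being assumed to vary like the others. Rxrb ranged from -0.186 (without 3-day +/+) to 0.420 (without 7-day +/+), with -0.0927 without 3-day Cy/Cy. Testing mutant ratios against 0, without the arrays labelled +/+, called 0 for Cy/Cy and 933 for Cy/+. It reversed Slc12a1 (-0.136), Fabp1 (0.243, and 0.00334 in Cy/+), Cyp3a2 (0.119), Fabp7 (0.277), Ampd1 (0.00066), Pkd1 (0.0241), Pkhd1 (-0.0561) and Rxrb (-0.347), with correlations between ages of 0.317 and 0.512. At an adjusted p of 0.10 the Cy/Cy ratio called 1, Cy/+ 2321 and the 3 pools 2188. A 2-fold rule at both ages gave 2198 for Cy/Cy, 2170 for Cy/+ and 5 for their difference. Every probe gave 8942 and 9157. At 1.5-fold the 6 arrays (+/+, Cy/+, Cy/Cy at 3, then 7 days) had 4886, 746, 112, 4179, 394 and 94 genes, and with the software's p of 0.01 6529, 1275, 236, 5891, 869 and 190; after subtracting the array labelled +/+ the mutant arrays had 2973, 3006, 2599 and 2546. With an estimated correlation camera called 0 lists in Cy/Cy and 0 in Cy/+ against +/+. In the reference, processed signals minus the 75th percentile listed 315 genes, and the Cy5 of the arrays labelled +/+ 818, where Ret (-0.353), Adcy8 (-0.781), Igfbp1 (0.228), Vnn1 (0.404) and Rhoxl (0.0192) reversed.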

Other observations

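The Cy3 reference on the 7-day array labelled +/+ gave higher lens signals than the Cy3 reference on the other 7-day arrays. The labels do not state whether these references were 1 pool, and the cause was not tested. Cryaa, a lens crystallin, had a normalized log2 Cy3 intensity of 11.64 there and 6.64 on the arrays labelled Cy/+ and Cy/Cy, Crygd 12.38 against 9.63 and 9.62, Cryba1 11.06 against 7.95 and 8.02, and Crygn 11.24 against 8.41 and 8.45. In Cy5 of that array the lens list stood 4.28 above the reference.

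The pools of each array also differed in how alike their channels were. Across genes, Cy5 and Cy3 of the same array correlated at 0.873 and 0.903 on the arrays labelled +/+ and at 0.991 to 0.998 on the other 4, and the Cy5 channels of both arrays labelled +/+ correlated with each other at 0.976. The 3-day and 7-day Cy5 pools labelled +/+ thus resembled each other more than either resembled its reference. The Cy3 channels of these arrays also stood apart. The 3-day one correlated at 0.988 and 0.986 with the other 3-day Cy3 channels, and at 0.990 with the 7-day one. The 7-day one correlated at 0.983 with each other 7-day Cy3 channel. The Cy3 channels of the arrays labelled Cy/+ and Cy/Cy correlated at 0.998 at 3 days and 0.999 at 7 days. Whether the references of an age were 1 pool is therefore in doubt.

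A hypothesis set before the result was seen held that the Cy5 RNA on the arrays labelled +/+ was less mature than its reference, so that genes rising from 3 to 7 days would be lower on them. The correlation across genes of the change between ages with the log2 ratio was 0.163 at 3 days and 0.0748 at 7 days, above the bound of -0.1, which argues against it as far as the age labels hold. With the ages exchanged both signs turn, so that the 3-day value would fall below -0.1 and the 7-day value stay above it, and neither would reach the -0.3 that the hypothesis needs. Sampling error of the shared reference pool, which would push the value up at 3 days and down at 7 days, cannot be told apart from these values, since both lay above 0. With the change between ages measured without the arrays labelled +/+, the correlations were 0.0634 and -0.0446, which have the signs that sampling error predicts but lie near 0.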
